A study of Mus musculus with 6 samples.

How the data were processed

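Total RNA from confluent cultures of mouse induced renal epithelial cells was sequenced in 6 libraries: Cre (Pkd1 knockout) and Flp (floxed, not deleted) cultures of clones 4, 7 and 21. Per the submitters' processing notes, the tools were Trim Galore 0.4.3.0, FastQC 0.67, STAR 2.5.2b-2, featureCounts 1.6.0.3 and DESeq2 2.11.40.1, with the genome builds mm10 and GRCm38. Strand setting, read layout and annotation release are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The authors deposited raw counts per Ensembl gene, whole numbers for 49671 genes in each library, with no normalization. The authors also deposited a comparison table with the mean of normalized counts (a signal over all libraries), the log2 fold change, its standard error, a test score and a p-value with its adjusted p-value. A positive fold change there was read as higher in Cre, since 95.6% of signs matched those computed here.

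Gene symbols and coordinates came from GENCODE release M21 on GRCm38, where 49326 of the 49671 identifiers had an entry and 345 had none. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low genes were removed with filterByExpr, TMM factors were computed, and edgeR's quasi-likelihood test was fitted with clone as a block and group as the tested term, leaving 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM values use TMM-scaled library sizes, and log2 ratios per clone use a prior count of 2. Standard errors were derived from the F statistic.

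The block follows the series' design, which sets each Cre clone against its own Flp clone. As a check, deviations from the group means correlated at 0.20, 0.11 and 0.30 within clones 4, 7 and 21. Between clones they correlated at -0.27 to 0.02. Deviations from a group mean cancel out over its clones, which ties these values to each other. As whole libraries, Flp clone 7 correlated at 0.983 with Cre clone 4 and at 0.970 with Cre clone 7. The pairing of clone 7 was therefore not clear from the counts. No pair of libraries agreed within sampling noise, with chi-square values per degree of freedom of at least 38.2. Xist and 4 Y-linked genes had at most 11 reads in any library and did not tell the clones apart.

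Before the data were examined, 24 biology lists, 10 lists for checks of cell type, RNA quality and labels, the alternatives and the rule for named genes were fixed. The rule took Pkd1 and Pkd2, then 10 genes higher and 10 lower in Cre. As none passed the threshold, these places went to genes with the smallest p, the same direction in all 3 clones, a mean of at least 1 CPM and an established symbol. It also took the member with the smallest p of each biology list. Some of the genes it took are not reported here. Lists were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, beside camera with an estimated correlation and fry.

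The count tests were tested on simulated data with 50 genes changed at each fold among 15014 genes. For the blocked comparison, edgeR recovered 6% of 1.5-fold, 44% of 2-fold, 88% of 4-fold and 96% of 8-fold changes with 11 false calls. DESeq2 recovered 22%, 54%, 90% and 96% with 45 false calls. Counts were simulated with the dispersion that edgeR had fitted for each gene, so variation beyond it was not covered. These shares may therefore not hold for the real libraries, where edgeR with the filter called 0 genes.

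The scan along chromosomes was added after the data were seen. Log2 ratios of genes with a mean of at least 5 CPM were centred per clone and summarised in bins of 10 Mb with at least 8 genes. A bin counted when its median, weighted by the root of its number of genes, passed the 95% level of the highest bin in 1000 shuffles of positions. Of 8 candidate segments, 5 were kept, those whose change point had a bootstrap interval no wider than a bin, a criterion also set after seeing them. On shuffled data with a planted log2 shift of 0.5, the scan found 9 of 9 planted bins and 0 others, and placed the change point with an error of 5588 kb. Intervals of medians are bootstrap intervals over genes, from 1000 draws.

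The alternatives were fits without the block, DESeq2 with and without it, limma-voom, 3 other normalizations, 2 other filters, other thresholds and leaving out each clone. Alternatives added after the data were seen were library depth as a covariate, leaving out the chromosome segments, and the overlap with the authors' deposited table for edgeR without the filter and with depth. Figures were drawn with matplotlib 3.10.9.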

Results

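RNA was sequenced from cultures of mouse induced renal epithelial cells, fibroblasts turned into tubule-like cells by kidney transcription factors. The cells carried a floxed allele of Pkd1, which encodes polycystin-1 and is the gene most often mutated in autosomal dominant polycystic kidney disease. For each of 3 clones, numbered 4, 7 and 21, a culture transduced with Cre recombinase and labelled as a Pkd1 knockout was set against a culture of that clone transduced with Flp recombinase, in which the floxed gene was kept, giving 6 libraries and 3 per group. Total gene counts were 41574605 in Cre clone 4, 25196120 in Flp clone 4, 29451753 in Cre clone 7, 40274665 in Flp clone 7, 46918341 in Cre clone 21 and 26758752 in Flp clone 21. The Cre library was the deeper in clones 4 and 21 and the shallower in clone 7. A count of 0 allowed up to 0.0639 CPM in the deepest library and 0.119 CPM in the shallowest, and these floors cover counting error only. The labels do not say that the clones came from separate animals, so p-values measure the spread between these clone pairs.

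The first comparison asked whether the targeted gene differed between the Cre and Flp cultures. Pkd1 (ENSMUSG00000032855, chromosome 17, 24549834 to 24596508, GRCm38) was at 123 ± 20.6 CPM in Cre and 198 ± 31.5 CPM in Flp (SD, n = 3). Cre was the lower in every clone, with log2 ratios of -0.45 in clone 4, -1.12 in clone 7 and -0.50 in clone 21. The fitted log2 fold change of Pkd1 was -0.69 (SE 0.16), with an edgeR adjusted p of 0.6065 after Benjamini-Hochberg adjustment. Pkd1 passed the threshold with DESeq2 and the same clone block (adjusted p = 0.0275) and in edgeR without a filter on low counts (adjusted p = 0.0224). Over all alternatives its adjusted p by edgeR, limma or DESeq2 ranged from 0.0224 to 1. The floxed exons 2 to 4 make up 314 of 14164 bases, or 2.22%, of the longest coding Pkd1 transcript, so counts over the whole gene checked the labels only in part. Pkd1 exons also overlap those of Tsc2, whose reads could not be told apart without strand. Pkd2, the gene of the partner channel polycystin-2, was at 254 ± 16.5 CPM in Cre and 255 ± 37.5 CPM in Flp (SD, n = 3), with a log2 fold change of 0.00 (SE 0.14).

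**Figure D1:**
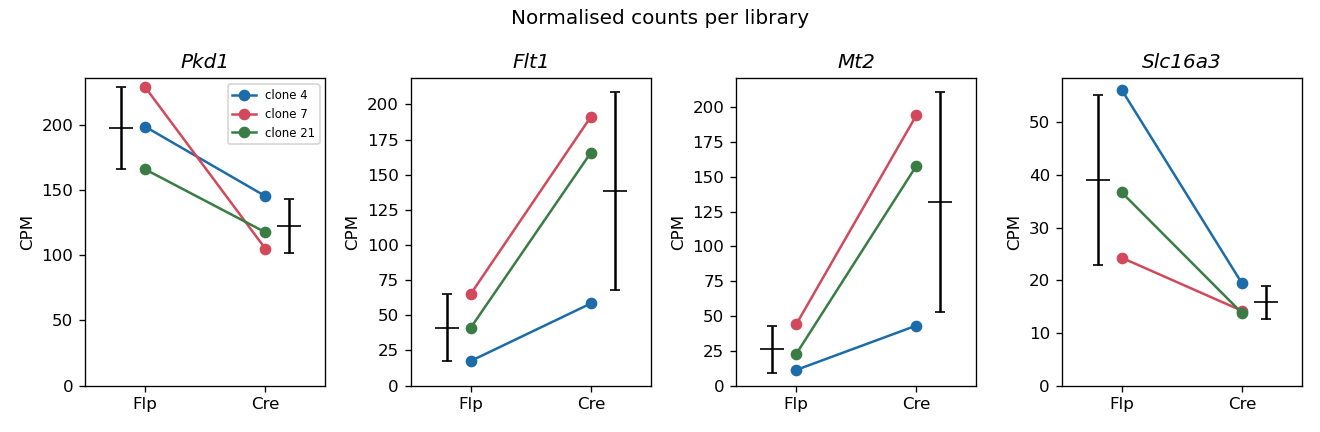
Normalised counts in CPM (y axes, linear from 0) of Pkd1, Flt1, Mt2 and Slc16a3 in the Flp and Cre library of each clone, joined by clone, with the mean and SD of each group of 3 beside the points. Pkd1 and Slc16a3 were lower and Flt1 and Mt2 higher in Cre in all 3 clones.

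The main comparison asked which other genes differed between Cre and Flp cultures when each clone was its own control. The genes with the strongest evidence of a higher level in Cre were Flt1, a receptor for vascular endothelial growth factor, and Mt2, a metal-binding metallothionein. Flt1 (chromosome 5, 147561604 to 147726011) was at 138 ± 70.5 CPM in Cre and 41.2 ± 23.8 CPM in Flp (SD, n = 3), a log2 fold change of 1.77 (SE 0.13), with clone ratios of 1.74, 1.55 and 2.01 in clones 4, 7 and 21. It lies in a stretch of chromosome 5 whose 50 expressed genes had a median log2 ratio of 0.996 in clone 4. Against the median of the 6 libraries, that stretch stood at -0.93 in Flp clone 4 and 0.02 in Cre clone 4. Mt2 (chromosome 8, 94172664 to 94173568) was at 132 ± 78.9 CPM in Cre and 25.9 ± 16.6 CPM in Flp (SD, n = 3), a log2 fold change of 2.30 (SE 0.19). Among genes lower in Cre, the lactate carrier Slc16a3 (chromosome 11, 120948480 to 120960868) was at 15.8 ± 3.15 CPM against 39.0 ± 16.1 CPM (SD, n = 3), and thrombomodulin, Thbd (chromosome 2, 148404466 to 148408188), at 29.0 ± 16.5 CPM against 68.4 ± 47.7 CPM (SD, n = 3). Thbd lies in a stretch of chromosome 2 with a median log2 ratio of -0.56 in clone 21. Against the median of the 6 libraries, this stretch stood at 0.48 in Flp clone 21 and -0.05 in Cre clone 21. The authors' deposited table lists mean normalised counts of 10551 for Mt2 and 1803 for Flt1, where the count files gave 2672 and 3043, so the levels of these genes depend on the source. None of these 4 genes passed the threshold of the filtered edgeR test, and all 4 passed with DESeq2 and the clone block and in edgeR without a filter on low counts, as did Flt1 with library depth as a covariate (edgeR adjusted p = 0.043).

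The other higher values among genes of one direction in every clone were Slc30a3, a zinc transporter, at a log2 fold change of 2.82, the aminopeptidase Enpep at 1.24 and the protocadherin Pcdh10 at 1.67. Aldh16a1 stood at 1.31, the protease inhibitor Serpine2 at 1.39, Slc18a1 at 0.91 and Atxn7l2 at 0.83. Tmem45b stood at 3.43 but was at 0.0211 CPM in Cre clone 21 and 0 in Flp clone 21. The other lower values were Fndc3c1 at -3.29, Habp2 at -2.15, Ctla2a at -1.78, the organic anion transporter Slco4a1 at -1.40, the hedgehog ligand Dhh at -0.91, Gdpd5 at -0.80, Cfap43 at -0.76 and Tmem37 at -0.66. Exons of Mt2, Aldh16a1, Pcdh10, Tmem45b, Habp2, Ctla2a, Cfap43 and Dhh overlap those of another annotated gene, so their counts are uncertain. For Cfap43 the authors' deposited table lists a mean of 21.8 and a log2 fold change of 0.02 (DESeq2 adjusted p = 0.9991), and for the overlapping Itprip, not among the genes tested here, a mean of 5678 and -0.65 (0.00115), so the value here cannot be assigned to Cfap43. All 20 higher and lower genes missed the threshold of the filtered edgeR test. With DESeq2 and the clone block 20 of the 20 passed (adjusted p from 2.5e-23 to 0.0382), and in edgeR without the filter also 20 (adjusted p from 1.9e-08 to 0.0258). These genes, Flt1, Mt2, Slc16a3 and Thbd included, had been picked by their small edgeR p in the same libraries. Their passes in other fits are therefore no separate evidence.

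**Figure D2:**
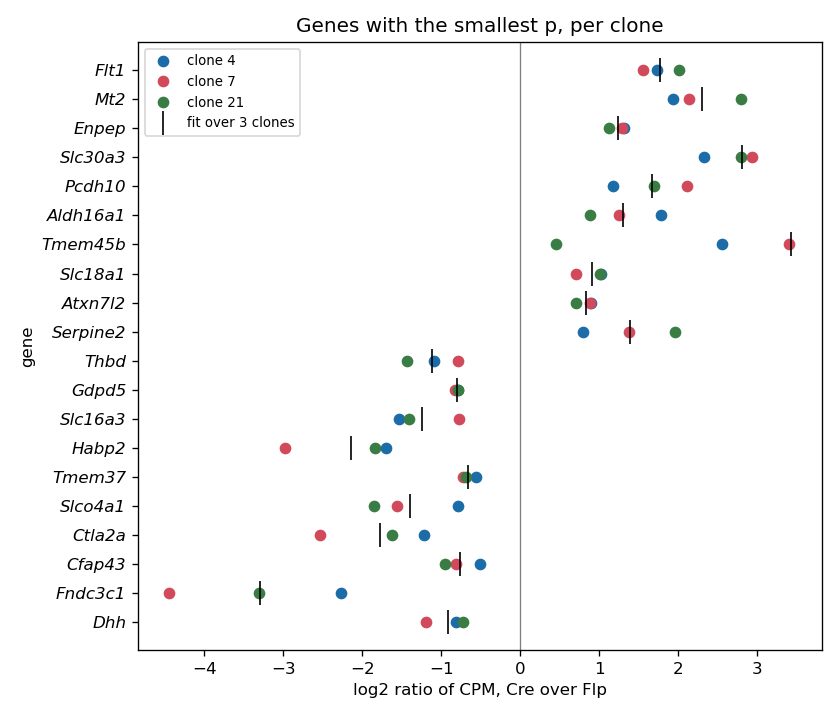
Log2 ratio of CPM, Cre over Flp (x axis), for the 10 higher and 10 lower genes with the smallest p (y axis), with points for the 3 clones and ticks for the fit over them. Every point of Enpep lay between 1.13 and 1.31, while those of Fndc3c1 ranged from -4.45 to -2.27.

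Of 15355 genes tested with edgeR and the clone block, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.2012, for Flt1. At an unadjusted p under 0.05, 1047 genes were counted, 544 higher and 503 lower in Cre, where 767.75 would be expected by chance. Without the chromosome segments described below, 871 of 14323 genes were counted. Genes that vary together can move such a count far from the chance value. With the Cre and Flp labels of clone 4 swapped it was 1068, so the excess alone is no evidence of an effect of Cre. DESeq2 with the clone block called 196 genes, 98 higher and 98 lower, DESeq2 without it 14, limma-voom with it 0 (1116 at an unadjusted p under 0.05), and edgeR without a filter on low counts 224. Of those 224 genes, 220 had also been tested with the filter and 160 were among the DESeq2 calls.

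The next comparison asked whether genes of a pathway or cell type differed together. Genes of cholesterol synthesis were lower in Cre, with a median log2 fold change of -0.48 over 22 measured members, of which 21 were negative and 18 lower in every clone. The member above 0, Fdft1 at 0.18, had clone ratios of -0.05, 0.73 and -0.13 in clones 4, 7 and 21, and lies in a distal stretch of chromosome 14 that was higher in Cre of clones 7 and 21. The log2 fold changes of the members Dhcr7, Cyp51 and Fdps were -0.45, -0.46 and -0.74. The clone medians of the list were -0.27 in clone 4, -0.31 in clone 7 and -0.68 in clone 21. The list passed limma's camera with a preset correlation of 0.01 (adjusted p = 4.0e-09) but not with an estimated correlation (adjusted p = 0.9986) or fry (adjusted p = 0.9284). Over all genes tested with edgeR 0 members passed, and 0 adjusted over the list alone, with 13 at an unadjusted p under 0.05.

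Glycolysis genes had a median log2 fold change of -0.22 over 20 members, 18 of them negative, with Slc16a3 at -1.24, the phosphofructokinase Pfkl at -0.56 and the glucose transporter Slc2a1 at -0.50. Pfkp, another phosphofructokinase, went the other way at 1.42. Oxidative phosphorylation genes had a median of -0.12, with 26 of 30 negative and Ndufa1, a subunit of respiratory complex I, at -0.53, but the clone 7 median was 0.03. By limma's camera with the preset correlation, the adjusted p was 0.00029 for glycolysis and 0.0051 for oxidative phosphorylation, and 0.9986 for each with an estimated correlation. The camera call of oxidative phosphorylation was lost without clone 4 (adjusted p = 0.5137), without clone 21 (0.0542) and with library depth as a covariate (0.121). The fit with depth gave clone 7 as much weight as clones 4 and 21 together. Adjusted over the list alone, 2 glycolysis genes passed, Pfkl and Slc16a3, and 0 genes of oxidative phosphorylation.

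**Figure D3:**
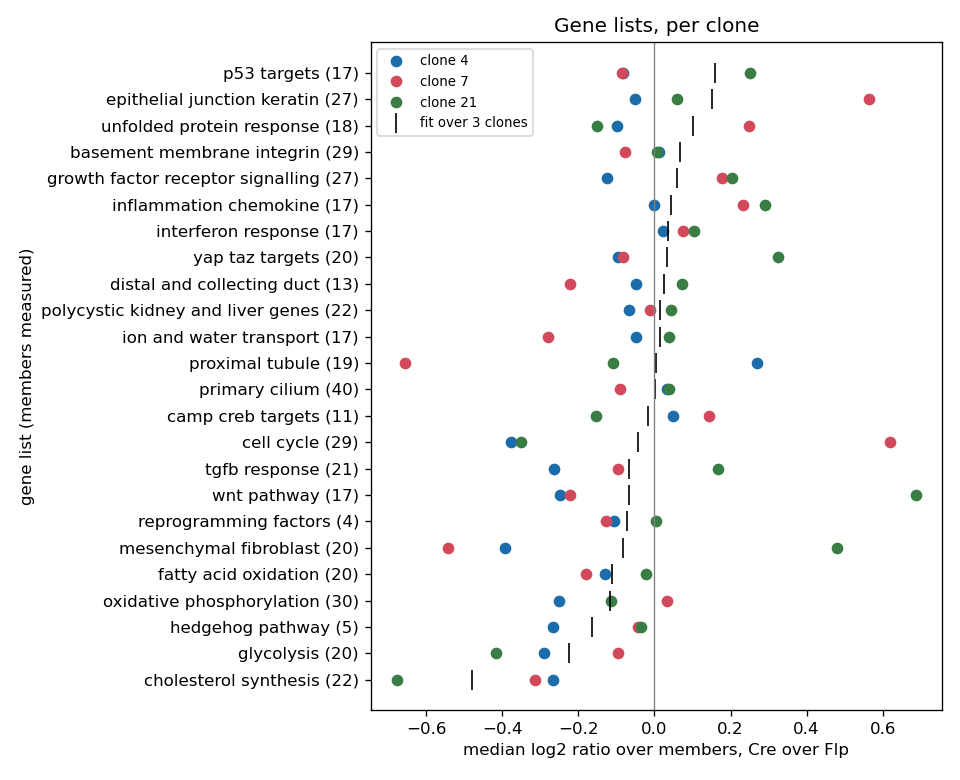
Median log2 ratio, Cre over Flp (x axis), over the measured members of the 24 gene lists (y axis, members in brackets), with points for the clones and ticks for the median of the fit. Cholesterol synthesis lay below 0 in every clone, while cell cycle medians were -0.38, 0.62 and -0.35 in clones 4, 7 and 21.

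The remaining 21 lists missed the threshold of the camera test, and no member of any list passed over all genes. Without clone 21, limma's camera put the epithelial junction and keratin (adjusted p = 0.000999, higher), mesenchymal (0.000684), TGF-beta response (0.0164), Wnt (0.0140) and fatty acid oxidation (0.0140) lists past the threshold, the last 4 lower in Cre, and without clone 7 the cell cycle list (1.6e-09, lower). With library depth as a covariate the epithelial junction and keratin list also passed limma's camera (adjusted p = 0.000471, higher). Its clone medians were -0.05, 0.56 and 0.06 in clones 4, 7 and 21. As that fit gave clone 7 more weight, a correction for depth cannot be told from that weight. All of these calls used the preset correlation, and with all libraries each of these lists had an adjusted p of 0.9986 by camera with an estimated correlation and 0.9284 by fry. TGF-beta response genes had a median of -0.07, yet 3 passed when adjusted over the list alone, among them Tgfbi at -2.02 and Pmepa1 at -0.53. Fatty acid oxidation had a median of -0.11 with Fabp3 at -1.45, and the epithelial junction and keratin list a median of 0.15 with Cldn1 at -1.47. Of 19 proximal tubule genes, Acsm2 passed adjusted over the list alone, at 1.86, and the list median was 0.00. The reprogramming factors had a median of -0.07, with Emx2 at 862 ± 40.6 CPM in Cre and 947 ± 38.5 CPM in Flp (SD, n = 3). The 40 primary cilium genes had a median of 0.00, with Ift88 at 0.75, and the 22 polycystic kidney and liver genes a median of 0.01. The hedgehog list had a median of -0.16. Medians of the mesenchymal, Wnt, cell cycle and cAMP target lists were -0.08, -0.07, -0.04 and -0.02, with Sparc at -0.26, Notum at -1.50, Bub1 at -0.44 and Pde10a at -0.35. Those of the YAP and TAZ target, basement membrane, p53 target, interferon and inflammation lists were 0.03, 0.07, 0.16, 0.04 and 0.04, with F3 at -0.50, Itgb5 at -0.82, Eda2r at 0.38, Stat2 at -0.59 and Icam1 at 0.52. The distal nephron, unfolded protein response, ion and water transport and growth factor lists had medians of 0.02, 0.10, 0.01 and 0.06, with Kcnj16 at 1.20, Creld2 at -0.27, Aqp1 at -2.81 and Fgfr3 at 0.62. Some of these values were not shared by every clone: Bub1 had clone ratios of -0.25, 0.20 and -1.29 in clones 4, 7 and 21, and in clone 4 the ratio was -0.23 for Kcnj16, 0.06 for Stat2 and -0.05 for Aqp1. The median, the mean and the camera direction differed in sign for the polycystic, cilium, proximal tubule, cAMP target, interferon and ion transport lists. Exons of Ift88, Emx2, Fabp3, Notum, Icam1, Fgfr3, Cyp51, Fdps, Fdft1, Pfkp and Slc2a1 overlap those of another gene, so these counts are uncertain too. Dhcr7, Cyp51, Fdps, Fdft1, Pfkl, Pfkp, Slc2a1 and Tgfbi were chosen after their values were seen.

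Markers of other cell types had list medians between 0 CPM and, for podocytes, 1.23 CPM. The most abundant were Nes at 662 CPM, Csf1r at 199 CPM, Synpo at 104 CPM, Flt1 at 89.9 CPM, Tnnt2 at 12.1 CPM and Klf4 at 2.34 CPM over all libraries. Median log2 fold changes were -0.48 for 3 endothelial, 0.20 for 2 haematopoietic, -0.18 for 6 muscle, -0.09 for 6 podocyte, 0.23 for 3 neural and 0.03 for 3 pluripotency markers tested. Immediate early genes had a median of 0.19 and histone genes 0.04. All 13 mitochondrially encoded genes were at 0 in every library, so their share could not serve as a check of RNA quality.

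The clones differed in which genes moved. Across genes, which are not independent replicates, the Cre over Flp log2 ratios correlated at -0.05 between clones 4 and 7, 0.09 between 4 and 21 and 0.24 between 7 and 21. The direction was the same in all 3 clones for 27.7% of genes, where 25% would be expected by chance. The clone took a mean of 43.0% of a gene's variance and the group 19.6%, where their degrees of freedom alone would give 40% and 20%. On the first principal component, the main axis of variation between libraries (35.7%), Cre lay above Flp in every clone. Cre and Flp stood at -17.9 and -52.0 in clone 4, 53.8 and 0.12 in clone 7, and 30.1 and -14.2 in clone 21. On the second (25.3%), Cre lay above Flp in clones 7 and 21 and below it in clone 4.

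Positions of genes, examined after the data were seen, showed that some neighbouring genes moved together. On chromosome 14 from 26413168 to 122918971, 295 genes had a median log2 ratio of 0.80 in clone 7 (95% interval 0.76 to 0.83) and 0.77 in clone 21 (0.73 to 0.80), against 0.11 in clone 4 (0.07 to 0.17). The cilium gene Ift88 lay in it, with clone ratios of 0.00, 0.86 and 1.37. In clone 21, 338 genes from 125247190 to the end of chromosome 2, a stretch that holds Thbd, Slco4a1, Pmepa1 and Bub1, had a median of -0.56. In clone 4, 50 genes of chromosome 5 from 143622447, with Flt1 among them, had a median of 0.996. In clone 7, 55 genes of chromosome 6 from 134035700 had a median of -0.47. Against the median of the 6 libraries, the stretches of chromosomes 2, 5 and 6 departed mainly in Flp. The chromosome 2 stretch stood at 0.48 in Flp and -0.05 in Cre of clone 21. The chromosome 5 stretch stood at -0.93 in Flp and 0.02 in Cre of clone 4. The chromosome 6 stretch stood at 0.33 in Flp and -0.10 in Cre of clone 7. The chromosome 14 stretch departed in Cre, at 0.73 and 0.65 in clones 7 and 21, against -0.06 and -0.11 in Flp. Nearer the start of chromosome 14, 56 genes had medians of -0.73 in Cre and -0.94 in Flp of clone 4 against the median of the 6 libraries, and 0.39 in Flp of clone 7. The chromosome 14 segment held 41 of the 98 genes that DESeq2 with the clone block called higher in Cre, and 2.61% of all genes tested. As the segment was found from the same ratios, a Fisher's exact test run on this share is void and its value is not given.

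**Figure D4:**
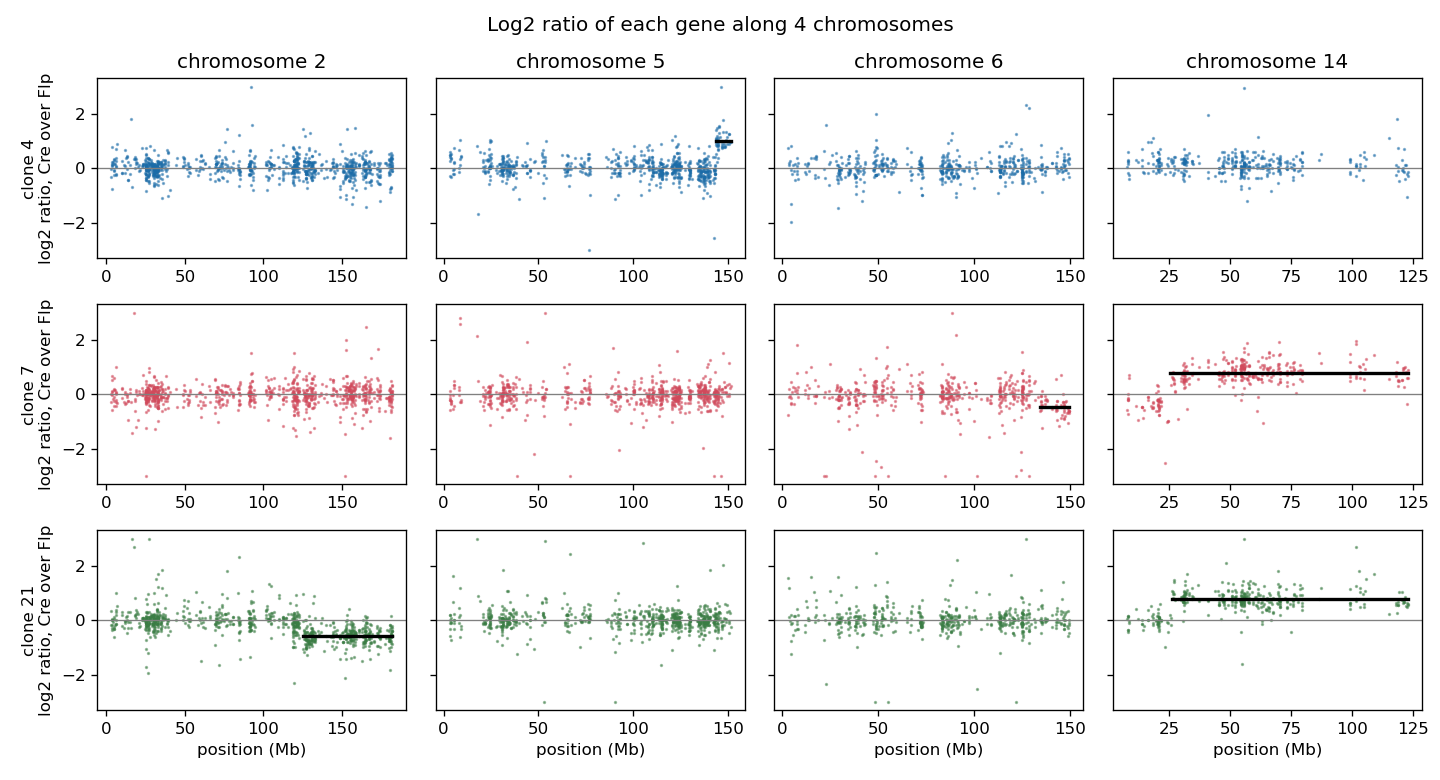
Log2 ratio, Cre over Flp (y axis, values beyond 3 drawn at 3), of each expressed gene against its position in Mb (x axis) on chromosomes 2, 5, 6 and 14, one row of panels per clone. Black lines mark the segment medians, such as 0.79 and 0.77 on chromosome 14 in clones 7 and 21.

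The authors' deposited table of the same comparison listed 178 genes at an adjusted p under 0.05 by DESeq2, 106 higher and 72 lower in Cre. Of the 174 calls matched by symbol to genes tested here, 174 had the same sign, 172 the same direction in all 3 clones and 173 an unadjusted edgeR p under 0.05. DESeq2 with the clone block shared 151 calls with the authors' deposited table, DESeq2 without it 12, and edgeR, which called no genes, 0. Without the filter on low counts, an overlap counted after the data were seen, edgeR shared 139. Pkd1 was listed in the authors' deposited table at a log2 fold change of -0.57 with a DESeq2 adjusted p of 0.037. Of the 104 higher calls in the authors' deposited table that were matched, 50 lay in the chromosome 14 segment. Both tests used the same libraries, so the overlap compares methods only.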

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

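Library depth as a covariate, leaving out the chromosome segments, and the overlap with the authors' deposited table without a filter were alternatives chosen after seeing the data. The count of changed genes was 0 in edgeR with the clone block and with no replicate block (smallest adjusted p = 0.9803), with limma-voom, 3 other normalizations, the CPM filter, stricter and looser thresholds, and without any clone (0 to 0) or the segments. DESeq2 with the replicate block gave 196 (98 higher, 98 lower), DESeq2 without it 14 (8 and 6), and depth as a covariate 7 (2 and 5). With no filter on low counts edgeR gave 224 (123 and 101), with prior degrees of freedom of 21.7 in place of 3.75. The cause of these differences was not tested. Pkd1 passed with DESeq2 and the block (-0.69) and with no filter (-0.68), was -0.47 to -0.81 without a clone, and missed the threshold in the other alternatives (highest adjusted p by edgeR 1). Overlap with the authors' deposited table was 151 and 12 genes for DESeq2 with and without the block, and 139 and 4 for edgeR with no filter on low counts and with depth. Lists past the threshold numbered 3, and 0 with an estimated correlation, 0 with fry and 2 to 7 without a clone, the highest without clone 21. With depth the number was 3, oxidative phosphorylation being lost and the epithelial junction list gained. Both changes could come from the larger weight of clone 7 in that fit. The same 3 lists passed without the block, which changed no other call. The sign held in every alternative for 43 of the 44 named genes. The exception was Pkd2, which had no clear direction: the Pkd2 log2 fold change was below 0 without the replicate block (-0.00719), with DESeq2 with (-0.00108) and without (-0.00990) the block, RLE (-0.00108), upper quartile (-0.00522), the CPM filter (-0.00222) and depth (-0.0726), and ranged from -0.16 to 0.15 without a clone.

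Of the lists, those called had the same direction in every alternative, and those below changed direction in some, with limma camera or fry adjusted p given. Without the replicate block these were proximal tubule (0.903) and unfolded protein response (0.904). With depth they were proximal tubule (0.682), distal nephron (0.825) and cell cycle (0.121). Without the segments they were primary cilium (0.877), YAP and TAZ targets (0.877) and unfolded protein response (0.991), and with fry primary cilium (0.928). Leaving out a clone turned the direction at least once for the following lists, with camera adjusted p from 0.925 to 0.963 for primary cilium, 0.000999 to 0.563 for epithelial junctions, 0.674 to 0.949 for proximal tubule, 0.706 to 0.963 for distal nephron and 0.000684 to 0.959 for mesenchymal genes. The range was 0.0164 to 0.811 for TGF-beta response, 0.340 to 0.828 for YAP and TAZ targets, 0.828 to 0.949 for basement membrane, 1.6e-09 to 0.663 for cell cycle and 0.0140 to 0.963 for Wnt. It was 0.957 to 0.965 for interferon, 0.175 to 0.811 for unfolded protein response and 0.0680 to 0.963 for growth factors. Depth limits low genes most, since a count of 0 allows up to 0.119 CPM.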

Other observations

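Chosen after the results were seen were the tests of the chromosome 14 segment, of depth and the segments for the cholesterol list, of the levels in the authors' deposited table, and of the gene and list counts under other splits, while the list tests and the DESeq2 and no-filter fits were planned. The test of the cholesterol list under other splits was set before its own result was seen. Mt1, a metallothionein like Mt2, was chosen after its values were seen. It was at 561 ± 417 CPM in Cre and 141 ± 62.5 CPM in Flp (SD, n = 3), with clone ratios of 0.85, 2.24 and 2.18, beside Mt2 at 1.94, 2.14 and 2.80. The adjusted p of Mt1 was 0.6065 with edgeR, 1.4e-07 with DESeq2 and the clone block and 1.2e-05 with edgeR and no filter on low counts.

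The distal chromosome 14 segment was higher in Cre of clones 7 and 21. Extra copies of the segment in these cultures stay open, since RNA does not count DNA copies and the segment was picked for its higher genes, which leaves no test of them here. An effect of Pkd1 loss of the same size in every Cre culture is argued against by clone 4. Its median was 0.11, with its interval below those of the other clones. The clone 4 interval was itself positive (0.07 to 0.17), so a smaller shift there stays open. The segment bounds came from clones 7 and 21, and the intervals cover genes of single library pairs, not cultures. A common origin of the Cre cultures of clones 7 and 21 cannot be decided here, since the values pointed both ways. Their difference followed that of their Flp cultures outside the segments (r = 0.2414 across genes, 95% interval 0.16 to 0.32). That r rests on single libraries and was read with bounds set after the data were seen. The matching r was 0.17 for clones 4 and 7 and 0.37 for clones 4 and 21. Over all tested genes, Cre clone 7 correlated at 0.978 with Cre clone 21 and at 0.970 with Flp clone 7. A high value across clones was not particular to this pair, as Cre clone 4 correlated at 0.983 with Flp clone 7. Cre clone 21 correlated at 0.977 with Flp clone 21. The Cre cultures of clones 7 and 21 also shared 112 genes outside chromosome 14 that stood apart from the other 4 libraries. Within clones 7 and 21 there were 31 and 64 such genes, and why was not tested.

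The cholesterol synthesis list was lower in Cre by camera with a preset correlation, with 0 of its 22 members past the edgeR threshold, and missed it with an estimated correlation (limma camera adjusted p = 0.9986) and fry (0.9284). Library depth is argued against only weakly: clone 7, whose Cre library was the shallower, had a list median of -0.31 (95% interval over members -0.42 to -0.10). This interval rests on 1 pair of libraries and on members that vary together (estimated correlation 0.39). It therefore does not measure the spread between cultures. The chromosome segments are argued against by position, as they held only 1 of the 22 members, Fdft1, the member above 0. The 21 members outside them had a median of -0.48. Members that vary together without regard to Cre and an effect of Pkd1 loss cannot be told apart: among the 3 other splits that part every pair, the list passed the camera threshold in 1, lower again, the split with clone 7 swapped (limma camera adjusted p = 0.00062), which follows library depth. A pass in another split had been named in advance as what varying together would give, but each such split keeps 2 of the 3 pairs as they were, so an effect of Cre in every clone could give it too, a limit of that test seen only after its result.

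The authors' deposited table and the count files differed in level for some genes: of 11411 genes with a table mean of at least 50, 285 were listed at least 2 times higher in the table, among them Mt2 with a mean of 10551 against 2672. Reads that overlap another gene and were left out of the count files are a candidate explanation. Of the 285 genes, 87.4% overlapped exons of another gene, against 34.7% of the rest (Fisher's exact test, two-sided, odds ratio 13.0, p = 3.65e-74). Overlap alone does not tell left-out reads from reads counted under the overlapping gene. Cfap43, with a mean of 21.8 in the authors' deposited table and so not compared, was at 165 CPM in the count files. Left-out reads cannot account for Flt1, which was lower in the table, at 1803 against 3043, and overlapped no exon of another gene. Genes lower in the table were not examined as a set. Another scaling of all genes is argued against by the median ratio of 0.994, and no biological explanation was tested.

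Too few splits exist for a share under 0.05. In each of the 4 splits that part all pairs edgeR called 0 genes, a count that any split would equal, so it says nothing. At an unadjusted p under 0.05, 2 of the 4 gave as many genes, with 1047 in the real split and 1068 in the highest other, that with clone 4 swapped. DESeq2 with the block called 196 genes in the real split and 92 in the highest other, so 1 of the 4 gave as many. For the lists, 3 of the 4 gave at least as many, with 3 lists in the real split and 7 in the highest other, reached with clone 7 swapped, which follows depth, and with clone 21 swapped. Without the block, 5 of the 10 splits of the 6 libraries gave at least the 716 genes of the real split at an unadjusted edgeR p under 0.05, and the highest other, 1514, set clone 4 with Flp clone 21 apart from the rest.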
